A study of Bos taurus with 6 samples.

How the data were processed

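Total RNA was extracted from 6 pools of day 7 embryos, 3 from heifers with a low and 3 from heifers with a high progesterone concentration during superovulation, per the labels' protocols. The labels' protocols give poly(A) selection, a library kit that they do not describe as strand-specific, 15 cycles of library amplification, and paired-end reads of 100 bases. They give an RNA integrity number between 5.0 and 8.3 with a mean of 6.2 over the samples, without a value for each pool. RNA of partial integrity and poly(A) selection both favour the 3' part of transcripts, which can make counts depend on transcript length. Without molecular identifiers, duplicate reads from amplification were counted as separate reads, so that depth alone overstates the counting precision.

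The submitters' processing notes name Trimmomatic, kallisto, edgeR and the cattle build ARS-UCD1.2, without a version for the tools or the role of each. The authors deposited estimated counts per Ensembl gene, not scaled between samples, of which between 18.6% and 22.9% were not whole in each library (tolerance 1e-06). The authors also deposited TPM values of the same genes, scaled to gene length and to the same total in each sample. Estimated counts divide reads between similar genes, so that near-identical copies are uncertain, and the sources used here do not state that the counting used strand, so that values of overlapping antisense genes are uncertain too.

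Both tables held 22127 genes, of which 19354 had a count in at least 1 library. The table paired 17706 genes with a symbol and left 4421 without one. A further 1366 were named through their Entrez identifier (18523 identifiers matched) in the RefSeq gene table of assembly ARS-UCD2.0, which is not the build of the files and was used for names only, so that no coordinates are given. No rows lacked a gene. The columns were matched to samples by the sample descriptions. No pair of libraries of a group agreed within sampling noise, since chi-square per degree of freedom over genes ran from 62.6 to 619.

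The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr with a minimum count of 10 and a minimum total of 15, TMM normalization, glmQLFit and glmQLFTest, treatment group only). The filter kept 16690 genes. The log2 fold change is high minus low P4, its SE is the fold change divided by the square root of F, and p was adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Levels are CPM with TMM-scaled library sizes, as mean ± SD. The common biological coefficient of variation was 0.534. Chance gives non-overlapping groups in 10% of genes for 3 against 3, and an exact permutation test of 3 against 3 pools cannot give a two-sided p below 0.1, so none is reported for single genes.

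The 31 gene lists of cell types, lineages and pathways were fixed before the data were examined, as were the tests, the rule for naming genes and most alternatives. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and adjusted over the 30 lists with at least 5 tested genes. The list of X-linked dosage and sex markers had fewer and was not tested. Alternatives were camera with an estimated correlation and fry. The naming rule took genes past the threshold first and, since fewer than 10 passed, the 10 higher and 10 lower genes with the smallest unadjusted p among those with a symbol in the table and a mean log2 CPM of at least 1. Up to 4 members of each list with the smallest unadjusted p and 14 genes set in advance could be named too. Some genes named in the results fall outside the rule and were chosen after their values were seen. These are HMGCS1, KLF6, CXCL8, MUC1, FOXJ1, COL1A1, KRT8, LOC782781 and LOC100140270.

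The alternatives were DESeq2 1.42.0, RLE normalization, no filter and a stricter filter (1 CPM in 3 samples), the replicate number as a block, each library left out in turn, limma-voom, and limma on log2(TPM + 1) and log2(TPM + 0.1) with genes at TPM of at least 1 in 3 samples. Alternatives chosen after seeing the data left out low P4 replicate 1 and high P4 replicate 2 together, added a marker score of epithelium or of leukocytes (the mean log2 CPM of the list) as a covariate, or removed a trend with effective length from each library before the list test. Effective length was taken from the ratio of the deposited count to TPM.

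The edgeR, DESeq2, limma-voom, log2(TPM + 1) and replicate block tests were run on simulated data with 200 changed genes before they were used. Camera and fry were run on simulated lists, and the other alternatives were not simulated. Simulated TPM took the same length for every gene, and no simulated library stood apart in its gene means. In simulated lists of 25 genes shifted by 0.5 on the log2 scale, camera with the preset correlation gave an adjusted p of 0.0001291. Fry gave 0.05535 and camera with an estimated correlation 0.2125, and each test called 0 of 30 unshifted lists. The simulated genes were drawn independently, so this check cannot show how often the preset correlation calls unshifted lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The replicate numbers were checked for pairing from the correlation of the libraries' deviations from their group means. No pairing was seen, but 3 libraries in each group are too few to exclude one.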

Results

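Gene expression was measured by poly(A) RNA sequencing in pools of cattle embryos collected on day 7 after artificial insemination of superovulated Holstein heifers. Superovulation is a hormone treatment that makes several follicles ovulate at once, and the heifers had either a low or a high concentration of progesterone (P4), the ovarian steroid that maintains pregnancy, while it was given. Each treatment had 3 pools, to which embryos had been allocated at random, so p-values measure the spread between pools and not between heifers. The estimated counts summed to 86640280, 71752647 and 57195427 in high P4 replicates 1, 2 and 3, and to 63319786, 91545413 and 79959437 in low P4 replicates 1, 2 and 3. Between 16514 and 18005 genes had a count in each library.

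Markers of the blastocyst were measured in all 6 libraries. POU5F1, the pluripotency factor of the inner cell mass, stood at 721 ± 68.0 CPM (counts scaled to a common library total, mean ± SD, n = 3) in high P4 and 666 ± 201 CPM in low P4 pools. CDX2 and GATA3, transcription factors of the trophectoderm, stood at 117 ± 8.002 and 134 ± 19.8 CPM in high P4 and at 117 ± 34.8 and 121 ± 28.3 CPM in low P4 pools. KRT8, the epithelial keratin of the trophectoderm, took between 0.592% and 0.88% of all counts in each library, and COX1, a mitochondrially encoded respiratory subunit, took between 2.61% and 5.03%.

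The libraries also differed in transcripts known as markers of cells other than the embryo. Low P4 replicate 1 held 15640 CPM of LTF (lactotransferrin, an antimicrobial secretory protein), against 599 CPM or less in each other library. It also held 1720 CPM of PIGR, the epithelial receptor that transports polymeric immunoglobulin, 512 CPM of WFDC2 and 320 CPM of MUC1, and FOXJ1, the regulator of motile cilia, reached 79.8 CPM there. Of the 14 measured markers of oviduct and endometrial epithelium, 12 were highest in that library, and 9 of the 14 reached 1 CPM in every library. Of the 21 measured markers of blood cells, 9 were highest in high P4 replicate 2, where the neutrophil chemokine CXCL8 stood at 258 CPM against 56.9 CPM or less elsewhere, and 7 were highest in low P4 replicate 1. Of the 14 measured stromal markers, 11 reached 1 CPM in every library, and 10 were highest in high P4 replicate 3, where COL1A1, a fibrillar collagen chain, reached 1018 CPM against 163 to 594 CPM elsewhere. The other 4 were highest in low P4 replicate 1, among them the stromal markers with the smallest unadjusted p, MGP (18.5 CPM, and 1.55 CPM in high P4 replicate 3) and FBLN1 (55.8 and 7.60 CPM).

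**Figure D1:**
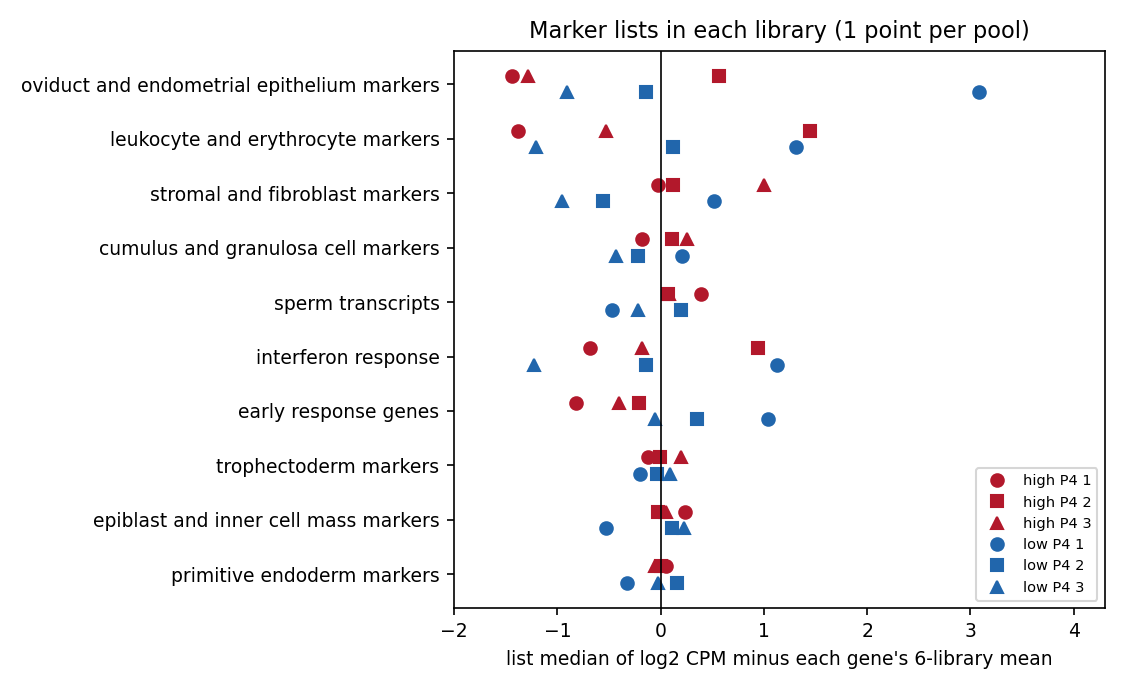
Marker gene lists in each library. The x axis gives the list median of log2 CPM minus each gene's mean over the 6 libraries, and each point is 1 pool (red, high P4; blue, low P4; circle, square and triangle, replicates 1, 2 and 3). Low P4 replicate 1 lies at 3.08 for the epithelium markers, high P4 replicate 2 at 1.44 for the leukocyte and erythrocyte markers, and all high P4 pools lie below all low P4 pools for the early response genes.

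The comparison of high with low P4 asked which embryonic transcripts differ with the progesterone concentration during superovulation. The early response genes, the transcription factors and feedback regulators that cells induce within minutes of a stimulus, had lower levels at high P4 in all 24 measured members. FOS stood at 102 ± 28.2 CPM in high P4 and 519 ± 473 CPM in low P4 pools, and EGR1 at 68.9 ± 10.1 and 294 ± 208 CPM (mean ± SD, n = 3 each). Low P4 replicate 1, the library with the high epithelium markers, set much of these low P4 means, with 1065 CPM of FOS and 535 CPM of EGR1 against 256 and 235 CPM of FOS and 178 and 170 CPM of EGR1 in the other low P4 pools. The interferon tau gene IFNT2, the pregnancy recognition signal of the trophectoderm, and ZSCAN4, a zinc finger gene of embryonic genome activation, had higher estimates at high P4, with 21.0 ± 4.27 against 9.68 ± 2.19 CPM for IFNT2 and 7.37 ± 1.10 against 3.24 ± 0.40 CPM for ZSCAN4. None of these genes passed the edgeR test after adjustment over all genes. Of FOS, EGR1, IFNT2 and ZSCAN4, DESeq2 called only IFNT2 (adjusted p = 0.04807).

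Of 16690 genes tested with edgeR's quasi-likelihood test, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.855. An unadjusted p under 0.05 was found for 788 genes, 339 higher and 449 lower at high P4, where 834 would be expected by chance. The 2 groups did not overlap in 1951 genes, 11.7% of those tested, and chance gives 10%. DESeq2 called 35 genes on the same counts, 10 higher and 25 lower, whereas limma-voom and limma on log2(TPM + 1) called 0. Counts of 16690 genes were simulated in a single draw from the means of these libraries and edgeR's estimates of their spread. The changed genes all had a mean log2 CPM above 1, so recovery among weaker genes was not measured. In these counts edgeR recovered 10 of 67 changes of 2-fold, 38 of 67 of 4-fold and 52 of 66 of 8-fold, with 0 false calls. DESeq2 recovered 26 of 67, 58 of 67 and 64 of 66 of these changes, with 75 false calls. The libraries did not separate by treatment, since the correlation of log2 CPM averaged 0.926 within groups and 0.925 between groups.

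Each direction was ranked by unadjusted p among genes with a symbol from the authors and a mean log2 CPM of at least 1. Genes without such a symbol were left out. Some with higher estimates had a smaller unadjusted edgeR p than all 10 named below, among them LOC782781 (log2 fold change 1.06) and LOC100140270 (1.52). DESeq2 called both. Among the 10 ranked genes with higher estimates at high P4, PLEKHG4 (ENSBTAG00000021570) had the largest log2 fold change, 1.31 with a standard error (SE) of 0.26. PLEKHG4, a guanine nucleotide exchange factor of Rho GTPases, stood at 13.4 ± 2.62 CPM in high P4 and 5.40 ± 0.82 CPM in low P4 pools. ZSCAN4 (ENSBTAG00000038947) followed with a log2 fold change of 1.19 (SE 0.28) and SLC7A6, a cationic amino acid exchanger, with 0.93 (SE 0.22). JCAD, a component of endothelial cell junctions, had 0.77 (SE 0.16), with 39.7 ± 0.23 against 23.3 ± 4.16 CPM. RAB7B, a GTPase of endosomal transport, had 0.64 (SE 0.14), and the remaining 5, PDRG1, ATG14 (an autophagy factor), PFDN2 (a prefoldin chaperone subunit), OSBPL7 and ZNF622, had estimates from 0.39 to 0.59. In all 10 every high P4 pool lay above every low P4 pool, which ranking by p itself favours, and in all 10 the edgeR adjusted p was 0.855.

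Among the 10 with lower estimates at high P4, TENT5C (ENSBTAG00000046509), a noncanonical poly(A) polymerase, had a log2 fold change of -1.69 (SE 0.26), with 2.81 ± 0.35 CPM in high P4 and 9.07 ± 0.94 CPM in low P4 pools. ITPKB (ENSBTAG00000053007), a kinase of inositol trisphosphate, had -1.39 (SE 0.22), with 10.8 ± 1.94 against 28.2 ± 5.65 CPM. MPIG6B, an inhibitory receptor of megakaryocytes, had -1.48 (SE 0.31). LRBA, a protein of vesicle trafficking, had -0.99 (SE 0.17), with 79.1 ± 3.23 against 157 ± 35.8 CPM. EPHB6 (an ephrin receptor without kinase activity), SHANK2 (a scaffold protein), ATF3 (a stress-induced transcription factor), AGRN (a basement membrane proteoglycan), GSE1 and GALNT7 had estimates from -0.94 to -0.54. In all 10 every high P4 pool lay below every low P4 pool, which the ranking again favours, and the edgeR adjusted p was again 0.855 in each. DESeq2 called 13 of the 20 genes, all 10 lower ones and 3 of the higher ones (PLEKHG4, JCAD and RAB7B).

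**Figure D2:**
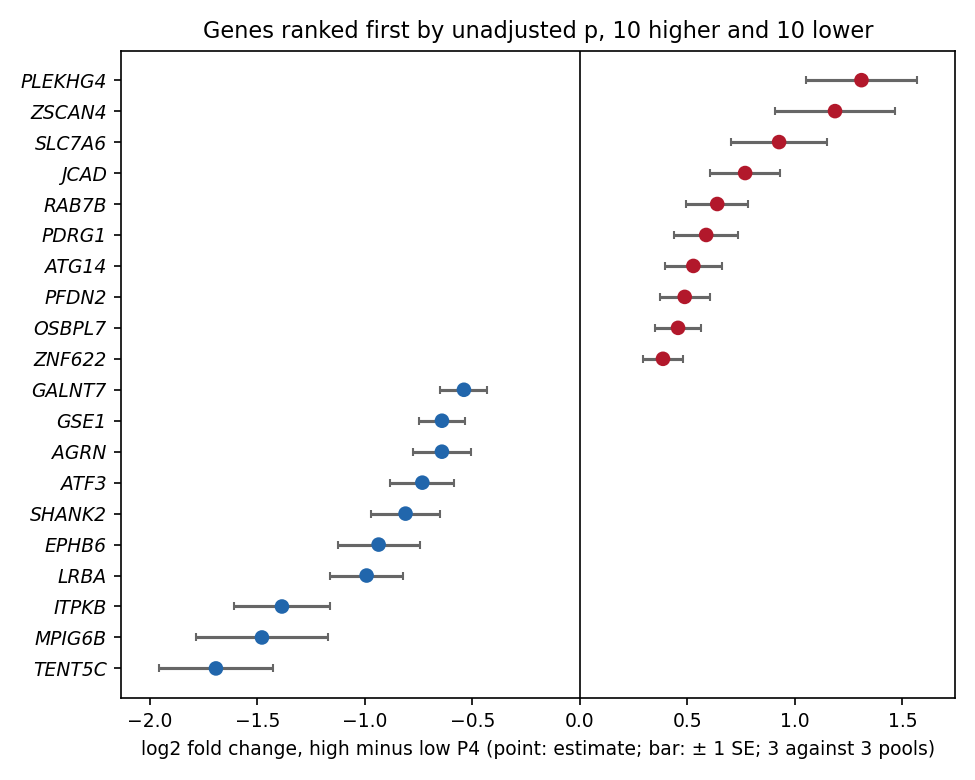
The 20 genes named by rank, 10 higher (red) and 10 lower (blue) at high P4. Each direction was ranked by unadjusted p among genes with a symbol from the authors and a mean log2 CPM of at least 1. Points are log2 fold changes of high minus low P4 and bars are ± 1 SE, from 3 against 3 pools. Estimates run from -1.69 for TENT5C to 1.31 for PLEKHG4, and all 20 have an edgeR adjusted p of 0.855.

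Of 31 gene lists fixed before the data were examined, 30 had at least 5 measured genes, and 6 passed an adjusted p of 0.05 in camera with a preset correlation of 0.01 between genes, 5 of them higher and 1 lower at high P4. With the correlation estimated for each list 0 passed, as with fry, a test of whether a list's genes move on balance in a single direction. The estimated correlations were 0.40 for the early response genes, 0.69 for ribosomal proteins, 0.77 for oxidative phosphorylation and 0.41 for cholesterol synthesis. They were 0.13 for genome activation and 0.0089 for maternal transcripts. List medians are differences of mean log2 CPM with a prior count of 2, high minus low P4. No member of any list passed over all genes in edgeR. The DESeq2 calls included the early response genes ATF3 and IER2 (adjusted p = 0.01261 each) and the trophectoderm marker IFNT2 (adjusted p = 0.04807).

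The early response genes formed the list shifted lower, with a median of -0.83 and an adjusted p of 9.745e-10. With an estimated correlation, the adjusted p was 0.8288. All 24 estimates were lower at high P4, 11 of them with an unadjusted p under 0.05, and 5 passed when adjusted over the list alone. These 5 were ATF3 (log2 fold change -0.73, SE 0.15), IER2 (-0.81, SE 0.17), EGR1 (-2.09, SE 0.46), FOS (-2.35, SE 0.62) and KLF6 (-0.61, SE 0.18). Low P4 replicate 1, the library with the high epithelium markers, held the most FOS (1065 CPM), EGR1 (535 CPM) and IER2 (324 CPM), and without it the list's median was -0.59 (adjusted p = 2.017e-05), while without low P4 replicate 3 it was -1.24 (adjusted p = 1.829e-11). The other low P4 pools held 256 and 235 CPM of FOS, against 86.3, 135 and 85.1 CPM in the high P4 pools.

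**Figure D3:**
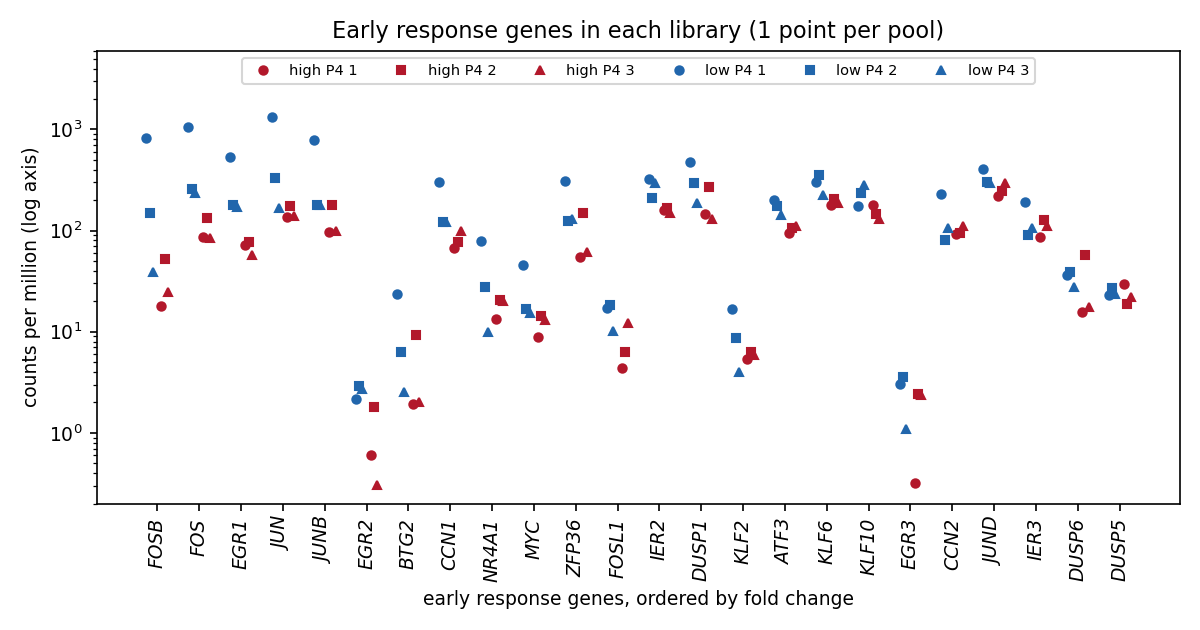
Early response genes in each library. The y axis is CPM on a log axis, each point is 1 pool (red, high P4; blue, low P4; circle, square and triangle, replicates 1, 2 and 3), and genes are ordered by log2 fold change. FOS lies between 235 and 1065 CPM in the low P4 pools and between 85.1 and 135 CPM in the high P4 pools.

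Genes of the protein synthesis and respiratory machinery made up the next lists, both shifted higher by small amounts. The 76 cytosolic ribosomal protein genes had a median of 0.17 (adjusted p = 1.091e-08), and the adjusted p was 0.854 with an estimated correlation. Of these, 73 had higher estimates at high P4, and 0 passed when adjusted over the list alone. RPL24 stood at 604 ± 51.3 against 484 ± 47.6 CPM and RPL22 at 259 ± 12.5 against 216 ± 8.74 CPM. The 76 nuclear genes of oxidative phosphorylation had a median of 0.18 (adjusted p = 5.747e-07, and adjusted p = 0.854 with an estimated correlation), with 69 estimates higher and 0 members past when adjusted over the list alone. UQCRH, a subunit of complex III, stood at 114 ± 9.91 against 88.6 ± 10.2 CPM, and NDUFA13, a subunit of complex I, at 86.1 ± 1.63 against 71.1 ± 5.48 CPM. Low P4 replicate 1 was the lowest library for the oxidative phosphorylation list, and without it the median was 0.05 (adjusted p = 0.2306), while without low P4 replicate 3 it was 0.30 (adjusted p = 4.394e-15). The 13 mitochondrially encoded genes had 12 lower estimates and a median of -0.12, without passing (adjusted p = 0.1464), and low P4 replicate 1 had the largest mitochondrial share of counts, 11.7% against 7.75% to 8.99% elsewhere. Without high P4 replicate 3 the mitochondrially encoded list passed as lower (median -0.19, adjusted p = 0.01802), and without low P4 replicate 1 its median was 0.0021 (adjusted p = 0.8108). Without low P4 replicate 2 the ribosomal median was 0.10 (adjusted p = 0.01648), and without low P4 replicate 3 it was 0.27 (adjusted p = 5.798e-14). With a trend of expression with transcript length removed from each library, neither the ribosomal list (median 0.06, adjusted p = 0.1093) nor the oxidative phosphorylation list (median 0.08, adjusted p = 0.06514) passed.

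The 24 measured genes of cholesterol synthesis and uptake had a median of 0.21 (adjusted p = 0.02628, and adjusted p = 0.854 with an estimated correlation). Estimates were higher in 20 and 0 passed when adjusted over the list alone. HMGCS1, an enzyme of early mevalonate synthesis, stood at 182 ± 61.5 against 135 ± 33.4 CPM, and NSDHL, an enzyme of late sterol synthesis, at 75.9 ± 10.5 against 60.7 ± 2.47 CPM, whereas SREBF2, the transcription factor that induces the pathway, stood at 265 ± 8.45 against 315 ± 25.1 CPM. High P4 replicate 3, the library with the high stromal markers, had the highest level of the list. Without it the adjusted p was 0.5612 (median 0.09), without low P4 replicate 2 it was 0.2866 (median 0.12) and without low P4 replicate 3 it was 0.0954 (median 0.20), whereas without high P4 replicate 1 it was 0.0006924 (median 0.31).

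Genes of embryonic genome activation and of the oocyte also had higher list medians at high P4. The 15 measured activation genes had a median of 0.22 (adjusted p = 0.02628, and adjusted p = 0.854 with an estimated correlation), with 13 estimates higher and 0 members past when adjusted over the list alone. Beside ZSCAN4, KLF17 stood at 13.97 ± 4.67 against 7.10 ± 1.62 CPM and POLR2A, the large subunit of RNA polymerase II, at 263 ± 19.7 against 215 ± 8.67 CPM, while KLF4 stood at 319 ± 38.9 against 414 ± 79.4 CPM. The 27 oocyte and maternal transcripts had a median of 0.45 (adjusted p = 0.03636, and adjusted p = 0.8288 with an estimated correlation), with 21 estimates higher and 0 members past when adjusted over the list alone. ZP2, a zona pellucida protein, stood at 1.18 ± 0.45 against 0.37 ± 0.20 CPM and KHDC3L, of the subcortical maternal complex, stood at 2.49 ± 1.51 against 1.05 ± 0.09 CPM. Most of the maternal transcripts lay near the floor, with a mean log2 CPM below 0, such as ZP2 (-0.32), MOS (-0.44) and NLRP5 (-1.45). Neither the activation genes nor the maternal transcripts passed with the stricter filter (1 CPM in 3 samples) or on log2(TPM + 1). Without low P4 replicate 1 neither list passed, with an adjusted p of 0.2015 for the activation genes (median 0.08) and 0.1019 for the maternal transcripts (median 0.25). Without high P4 replicate 1 the adjusted p was 0.1419 (median 0.15) and 0.2107 (median 0.12), and without low P4 replicate 2 it was 0.07963 for the maternal transcripts (median 0.46). The activation genes had a median of 0.31 (adjusted p = 0.01012) without low P4 replicate 3, and without high P4 replicate 2 the maternal transcripts had a median of 0.47 (adjusted p = 0.03466).

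**Figure D4:**
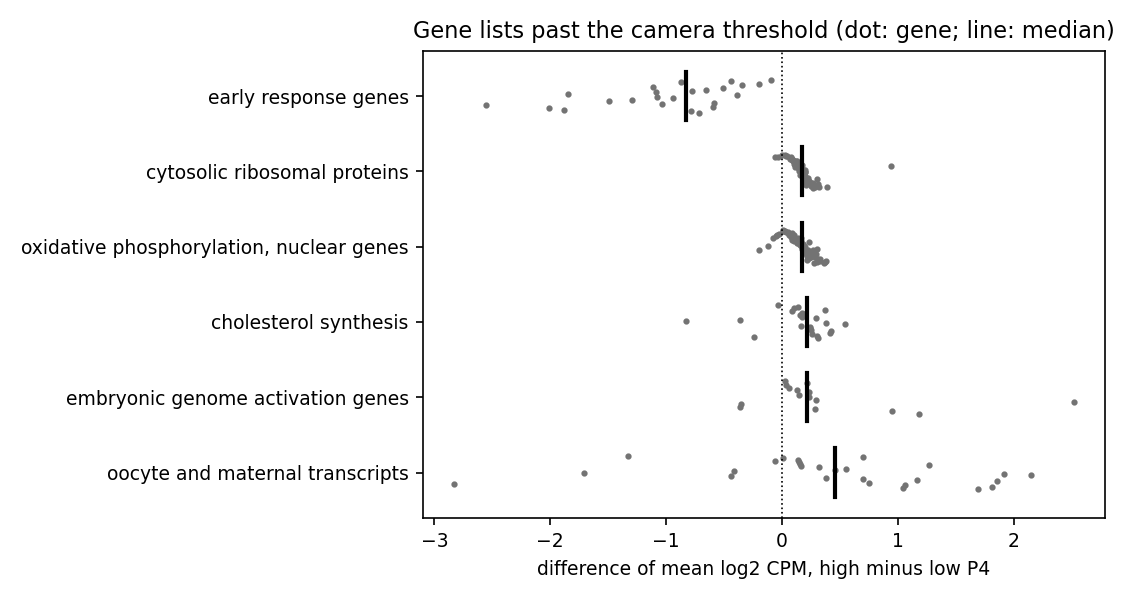
The 6 gene lists past the camera threshold. The x axis gives the difference of mean log2 CPM, high minus low P4, each dot is a gene and each vertical line is the list's median, which runs from -0.83 for the early response genes to 0.45 for the oocyte and maternal transcripts. No list passed with an estimated correlation.

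The lineage lists did not pass with all 6 libraries. The 24 trophectoderm markers had a median of 0.06 (adjusted p = 0.2373), with 13 estimates higher and 11 lower, and the median was -0.04 without high P4 replicate 3 and 0.16 without low P4 replicate 3, without passing. IFNT2 (ENSBTAG00000053027) had a log2 fold change of 1.12 (SE 0.25) and IFNT3 of 1.10 (SE 0.36), and in both every high P4 pool lay above every low P4 pool. These 2 genes are near-identical copies, so that the share of reads given to each is uncertain. The 23 epiblast and inner cell mass markers had a median of 0.14 (adjusted p = 0.1663), which was 0.31 (adjusted p = 0.01105) without low P4 replicate 3 and -0.11 without low P4 replicate 1, and NANOG stood at 42.1 ± 4.54 against 42.9 ± 10.3 CPM. The 18 primitive endoderm markers had a median of 0.06 and a mean of -0.18 (adjusted p = 0.7505), and a median of -0.08 without low P4 replicate 1 and 0.14 without low P4 replicate 3, with GATA6 at 380 ± 63.8 against 424 ± 146 CPM. The genes of blastocoel formation and cell junctions (median -0.15, adjusted p = 0.2373) and of cell cycle and DNA replication (median 0.09, adjusted p = 0.2157) did not pass either. The junction list passed as lower without low P4 replicate 1 (median -0.18, adjusted p = 0.02137), and without low P4 replicate 3 its median was -0.07 (adjusted p = 0.9739). The cell cycle list passed as lower without low P4 replicate 1 (-0.11, adjusted p = 0.02944) and as higher without low P4 replicate 3 (0.22, adjusted p = 0.001234).

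The receptors and enzymes of steroid hormones did not pass as a list (23 genes, median -0.29, adjusted p = 0.39). The median was 0.02 (adjusted p = 0.9715) without low P4 replicate 1, -0.10 without high P4 replicate 1, -0.12 without high P4 replicate 3 and -0.34 without low P4 replicate 3. PGR, the nuclear progesterone receptor, had a log2 fold change of -1.96 with an SE of 1.68, and its highest level, 9.79 CPM, was in low P4 replicate 1. That library also held 134 CPM of the estrogen receptor ESR1, against 11.8 CPM or less elsewhere. PGRMC1, a membrane-associated progesterone-binding protein, stood at 81.2 ± 11.8 against 100 ± 21.9 CPM. The growth factor signalling list had a median of -0.17 (adjusted p = 0.09957), with 23 of 32 estimates lower, among them the WNT receptor FZD5 at 16.4 ± 7.15 against 29.7 ± 2.80 CPM. That list's median was -0.29 (adjusted p = 0.08704) without high P4 replicate 2 and -0.15 (adjusted p = 0.1197) without low P4 replicate 2. Of 19 measured imprinted genes (median 0.10, adjusted p = 0.4072, and median -0.02 without low P4 replicate 3), IGF2R, the receptor that clears insulin-like growth factor 2, stood at 147 ± 11.2 against 183 ± 15.9 CPM. The maternal genes ZAR1 and GDF9 were under 1 CPM in every library, and SOX2, XIST and H19 were not analysed here.

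The metabolic and stress lists did not pass with all 6 libraries. Adjusted p was 0.7135 for glycolysis (median 0.08), 0.7974 for lipid droplets and fatty acid metabolism (0.03), 0.6465 for amino acid and nutrient transporters (0.13), 0.5745 for antioxidant defence (0.05), 0.7974 for lysosome and autophagy (-0.05) and 0.8396 for extracellular matrix and adhesion (-0.02). None of these lists passed when any 1 library was left out, and the median changed sign for glycolysis (-0.02 without high P4 replicate 3), lysosome and autophagy (0.02 without low P4 replicate 3) and extracellular matrix (0.05 without high P4 replicate 1). The transporter median was 0.02 without high P4 replicate 2, and also without high P4 replicate 3. Antioxidant defence had a median of 0.16 without high P4 replicate 1 and 0.01 without low P4 replicate 3. Among the transporters, SLC7A6 stood at 18.1 ± 0.10 against 9.54 ± 2.22 CPM and SLC1A5, a glutamine transporter, at 86.6 ± 11.03 against 60.7 ± 8.76 CPM, whereas SLC38A2 stood at 157 ± 13.2 against 214 ± 16.1 CPM. The heat shock and unfolded protein response list had a median of -0.01 and a mean of 0.04 (adjusted p = 0.8102). Its median was -0.09 (adjusted p = 0.7967) without low P4 replicate 1 and 0.01 (adjusted p = 0.806) without high P4 replicate 2. The apoptosis list had a mean of -0.04 but was ranked higher by camera (adjusted p = 0.7135), with GADD45A, a DNA damage response gene, at 92.8 ± 14.1 against 133 ± 5.41 CPM. The genes of DNA methylation and histone modification had a median of -0.03 (adjusted p = 0.7505), which was -0.16 (adjusted p = 0.02843) without low P4 replicate 1, 0.07 (adjusted p = 0.5408) without low P4 replicate 3 and 0.01 (adjusted p = 0.752) without high P4 replicate 3. The interferon response list had a median of -0.02 and a mean of 0.06 (adjusted p = 0.7974), and its highest libraries were low P4 replicate 1 and high P4 replicate 2, those with the most leukocyte markers. Without low P4 replicate 1 it passed as higher (median 0.62, adjusted p = 0.02137), and without low P4 replicate 3 its median was -0.31.

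None of the lists of other cell types passed with all 6 libraries. The epithelium markers had a median of -1.32 (adjusted p = 0.09957), which was -0.09 (adjusted p = 0.8108) without low P4 replicate 1. The list passed as lower without high P4 replicate 2 (-1.98, adjusted p = 0.03466), low P4 replicate 2 (-1.77, adjusted p = 0.02907) or low P4 replicate 3 (-2.07, adjusted p = 0.008435). The stromal markers had a median of 0.66 (adjusted p = 0.09957), and without low P4 replicate 1 the median was 0.97 and the list passed (adjusted p = 0.0009242), whereas without high P4 replicate 3 the median was 0.34 (adjusted p = 0.3965). The leukocyte and erythrocyte markers had a median of -0.31 but were ranked higher by camera (adjusted p = 0.7974), and without high P4 replicate 2 their median was -1.29 (adjusted p = 0.04238), while without low P4 replicate 1 it was 0.49 (adjusted p = 0.2306). The cumulus and granulosa cell markers (median 0.22, adjusted p = 0.2157) and the sperm transcripts (median 0.57, adjusted p = 0.2157) did not pass, with AMH, a granulosa cell hormone, at 2.81 ± 1.14 against 1.24 ± 0.70 CPM. The sperm median was 0.18 (adjusted p = 0.5254) without low P4 replicate 1 and 0.75 (adjusted p = 0.1185) without low P4 replicate 2. The cumulus list passed as higher without low P4 replicate 1 (median 0.43, adjusted p = 0.02137), whereas its median was -0.05 (adjusted p = 0.9531) without high P4 replicate 3 and 0.0041 without low P4 replicate 3.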

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

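The marker-score covariates, the joint removal of 2 libraries and the length correction were chosen after the data were seen. The count of genes past the threshold, 0 in edgeR, was 35 with DESeq2, 1 without low P4 replicate 1 and high P4 replicate 2 (S100A9), 3 with the epithelium score as a covariate, and 0 to 0 without each library in turn. Every other setting tried also gave 0. The cause of the higher counts was not tested, although in the simulation DESeq2 recovered more changes than edgeR (58 against 38 of 67 at 4-fold) and made 75 false calls against 0. Genes with an unadjusted p under 0.05 numbered 1120 with DESeq2, 385 with the replicate block, 1434 without low P4 replicate 1 and 470 without high P4 replicate 3. The 6 lists past the threshold became 0 with an estimated correlation and 0 with fry, and ran from 4 to 9 without each library in turn. Of 17 alternatives, the early response genes passed in 15 (adjusted p 3.152e-12 to 0.8288), the ribosomal proteins in 14 (5.798e-14 to 0.8667), oxidative phosphorylation in 11 (4.394e-15 to 0.8667), cholesterol synthesis in 12 (0.0006924 to 0.8667), genome activation in 8 (0.01012 to 0.854) and maternal transcripts in 6 (0.006106 to 0.8288). None of the 6 medians changed sign. The estimated correlation and fry ended the call in all 6 lists. Every other alternative used camera with the preset correlation of 0.01, so the counts of passes rest on that form of the test. For the maternal transcripts the estimated correlation was 0.0089, below the preset, yet the unadjusted camera p rose from 0.007271 to 0.05331. A larger correlation therefore does not account for the lost call of that list. The cell cycle list passed as lower without low P4 replicate 1 (-0.11) and as higher without low P4 replicate 3 (0.22), the leukocyte list passed as lower without high P4 replicate 2 (medians -1.29 to 0.49 over the libraries left out), and the cause was not tested beyond the library left out. No pairing by replicate number was seen. Same-number correlations were -0.29, 0.0057 and 0.2, not every library correlated best with its own number, and the replicate block gave 0 genes and 6 lists. With 3 libraries in each group, a pairing cannot be excluded. The libraries held 57195427 or more counts each, and 10 of 67 simulated 2-fold changes were recovered.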

Other observations

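The genes and tests below were chosen after the data were seen, except the splits of the libraries. For the splits, the leukocyte test of the early response genes and the length test, the deciding outcomes were written before the result was seen. Low P4 replicate 1 held 1480 genes more than 2-fold above every other library, against 15 to 227 in each of the others. They included the immunoglobulin joining chain JCHAIN (565 CPM, next library 5.48), the secreted airway and gland protein BPIFB1 (3020 against 71.9 CPM), the peptide GRP (3370 against 88.9 CPM), the chaperone CLU (3400 against 149 CPM) and the water channel AQP5 (125 against 5.22 CPM). High P4 replicate 2 had 204 such genes, among them IL1B (329 against 53.8 CPM), its antagonist IL1RN (711 against 114 CPM), MEFV (135 against 11 CPM) and CXCR1 (80.7 against 17.4 CPM), genes of neutrophils and activated myeloid cells. S100A9, a calprotectin subunit of neutrophils, stood at 14.4 CPM there, at 7.17, 9.08 and 8.98 CPM in the low P4 pools, and at 0.02 CPM in the other 2 high P4 pools. High P4 replicate 3 had 227, with LUM at 34.3 against 17.5 CPM and MMP2 at 40 against 21.8 CPM.

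Some genes outside the fixed lists, chosen from the DESeq2 calls, had lower estimates at high P4. PPP1R15A, the phosphatase subunit that ends the integrated stress response, stood at 93.2 ± 17.8 against 198 ± 59.8 CPM, ATP8A1, a phospholipid flippase, at 14.1 ± 1.59 against 34.1 ± 12.5 CPM, and PLA2G4A, the phospholipase that releases arachidonic acid, at 9.38 ± 0.14 against 16.9 ± 2.23 CPM (n = 3 each). DESeq2 called all 3, and edgeR gave an adjusted p of 0.855. ADPRM took between 1.08% and 4.4% of all counts, with the largest share in high P4 replicate 3.

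The epithelium pattern of low P4 replicate 1 was weighed against 3 explanations. A library that holds another tissue in place of embryos would lack embryonic transcripts, but the 47 trophectoderm and epiblast genes had a median log2 difference of -0.362 from the other libraries (95% bootstrap interval over genes -0.5201 to -0.239). Low P4 as a cause acting on every pool stays open: low P4 replicates 2 and 3 differed from the high P4 mean by a median of 0.0924 (-0.4818 to 0.7813), but by 0.684 (0.02398 to 1.478, higher in 11 of 14 genes) without high P4 replicate 2, whose epithelium score of 3.50 lay above those of low P4 replicates 2 and 3 (2.65 and 1.87). Epithelial cells recovered with the embryos are a candidate source that these data do not decide, since the share of 85.7% of the 14 genes highest in low P4 replicate 1 restates the pattern. The tissue, the oviduct or the uterus, was not tested.

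The lower early response genes at high P4 were weighed against cells of other types. Without low P4 replicate 1 the list's median was -0.591 (95% bootstrap interval over members -0.6654 to -0.3891), and with the leukocyte score as a covariate it was -0.666 (-0.9166 to -0.428), so neither source accounts for the whole shift. The intervals cover members, not pools, and the nearest pools, high P4 replicate 2 and low P4 replicate 3, lay at -0.21 and -0.05. The time from collection to lysis, which these genes are known to follow, and the treatment stay open and untested.

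The higher ribosomal protein and oxidative phosphorylation genes are short transcripts, and across 16690 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.15 with effective length. Among 10000 random lists matched on effective length and mean expression, the ribosomal median lay at percentile 86.37 and the oxidative phosphorylation median at percentile 94.86, while both lay at percentile 100 among lists matched on expression alone. A length trend, as RNA integrity or fragment size can give, is consistent with both shifts, and removing it left medians of 0.06 (adjusted p = 0.1093) and 0.08 (adjusted p = 0.06514). Epithelial cells in low P4 replicate 1 do not account for the ribosomal shift, which was 0.149 without that library (0.1298 to 0.1661), and cannot be told apart from other causes for oxidative phosphorylation, at 0.053 (0.01429 to 0.09668), because that median lies between the bounds set for and against them. Treatment stays open, since the correlation of library deviations with length was lower in the high P4 pools (-0.026, -0.072 and -0.16) than in the low P4 pools (0.028, 0.12 and 0.046).

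The 10 ways to split the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest other split 8, and a count of 0 is met by all 10 splits by construction, so that this comparison says nothing. For an unadjusted p under 0.05 it gave 788, and 3 of the 10 splits gave as many, up to 2410. For lists it gave 6, and 9 of the 10 splits gave as many, up to 12. The split with 2410 genes set high P4 replicate 1 and low P4 replicates 2 and 3 against the rest, several times the real count, which points to a structure of the samples other than treatment. The split with 8 genes set high P4 replicates 1 and 3 and low P4 replicate 3, the libraries with the lowest leukocyte scores (0.22, 0.68 and 0.97), against those with the highest (3.08, 2.89 and 2.04). The early response list had its smallest p in the real split, and it passed in 6 of the 10 splits. Its median was larger in absolute size in another split, 1.045 against 0.829 in the real one.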
